A study of Bacillus subtilis with 9 samples.

How the data were processed

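RNA was sequenced from dormant spores of Bacillus subtilis PS533, a derivative of strain 168 that carries the plasmid pUB110. Per the labels, spores were made at 37 °C on agar plates or in liquid culture of the same sporulation medium, harvested, and cleaned for 7 days with density-gradient centrifugation (highly purified), with fewer washes (less well purified), or for 1 day. Some were decoated, a chemical extraction that removes much of the protein coat, before RNA extraction. Libraries were stranded mRNA libraries read as short paired ends. The 9 libraries fall into 6 groups: intact highly purified plate spores (3 libraries), intact less well purified liquid spores (2), intact highly purified liquid spores (1), decoated 1-day plate spores (1), decoated 7-day plate spores (1) and decoated 7-day liquid spores (1).

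The authors mapped the reads with Bowtie, whose version is not given in the sources used here. The deposited tables give counts, as whole reads per feature, and these carry no normalisation. They list reads for 4325 coding sequences and 4536 genes, and 4322 of the coding sequences have the same count under both feature types. The deposited RPKM values are scaled by feature length and by the total reads of the same feature type. The deposited TPM values have the same fixed sum within each feature type, coding sequences and genes apart. How reads were assigned to features, whether strand was used and how reads that fit several places were treated are not given in the sources used here. The 8861 features were all paired by locus and name with the reference annotation of assembly ASM904v1, and 65 coding sequences without a symbol are named by locus tag. Gene lengths are coding lengths.

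From the counts of coding sequences, TPM and the percent of coding reads were computed for each library (numpy 2.4.6, pandas 2.3.3); the computed TPM differed from the deposited values by at most 0.005. The 210 structural RNA features were left out of the fits, except in the alternative with all features. Intervals for shares in single libraries are 95% Wilson intervals (scipy 1.17.1), and a count of 0 was taken to allow up to 3 counts. These intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Odd counts made up 10.6% to 27.5% of nonzero counts under 1000 in the intact libraries other than plate replicate 1 (42.3%), against 43.5% to 49.7% in the decoated ones. Counting both mates of a pair would make counts even, and whether this was done is not given in the sources used here. If it was, reads there number up to 2 times the fragments, floors are too low, intervals too narrow, and counts are not on 1 scale with those of decoated libraries; shares within a library would hold. Coding reads per library ranged from 635129 to 7355997, so 3 counts correspond to 4.72 CPM (counts scaled by the library total) in the smallest library and 0.408 in the largest.

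The test chosen before the data were examined was edgeR 4.0.16 (R 4.3.3), quasi-likelihood with TMM factors, in 1 fit of the 6 groups. It covered the 2785 coding sequences with at least 10 counts in at least 3 libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The SE given with edgeR changes, here and in the added fit below, is back-calculated. It is the absolute log2 change divided by the square root of the F statistic. The 8 contrasts were plates against liquid in intact highly purified spores, in decoated spores and against less well purified liquid spores, less well against highly purified liquid spores, decoated against intact spores in each medium, 1 against 7 days of purification, and the interaction of medium with decoating. Replicates are not stated to be separate cultures, so p-values measure the spread between these libraries. The 4 groups with 1 library were assumed to vary like the 2 groups with replicates, which leaves 3 residual degrees of freedom.

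That fit was dominated by genes with few reads: its common dispersion was 1.184, and its TMM factors ran from 0.247 to 7.665. An added fit, chosen after seeing the data, took the 52 coding sequences with a mean TPM of at least 100 over the 9 libraries, with TMM factors computed within them (0.571 to 1.652) and a common dispersion of 0.025. Its log2 changes are given relative to the median change of the 52 genes unless said otherwise. The SE and adjusted p printed beside them, and the calls, come from the test of the change before this median is subtracted. That median was −0.19 (log2) for plates against highly purified liquid spores, −0.19 against less well purified ones, 0.047 in decoated spores, −0.022 for purity, 0.080 and 0.12 for decoating in plate and liquid spores, −0.090 for purification time and 0.15 for the interaction. The same 52 genes were also scaled to library size alone and to rnpB, the RNA of RNase P.

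Both fits were tested on simulated data of these group sizes. With 200 of the 2785 genes changed, the all-gene fit recovered 13.6% of 64-fold changes for plates against highly purified liquid spores, 53% against less well purified ones, and 0% for decoated spores. The 52-gene fit recovered 57.1% or more of 2-fold changes and 100% of 4-fold changes in every contrast tested, with at most 1 false call. Each rate of the 52-gene fit rests on 6 or 7 genes, and the interaction was not simulated. Apart from the changed genes, the simulated libraries shared 1 mean composition. False calls from differences in composition between libraries were therefore not tested.

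The 20 gene lists fixed before the data were examined cover small acid-soluble spore proteins, germination proteins, other forespore genes under sigma G, early forespore genes under sigma F, mother cell genes under sigma E and sigma K, ribosomal proteins, translation factors, glycolysis, the TCA cycle, ATP synthesis and respiration, flagella and chemotaxis, heat shock, the sigma B stress response, RNA decay, biofilm and cannibalism, early sporulation, competence, cold shock and the PBSX prophage. The 21 list genes whose names found no match include coxA, tlp and ypeB, and such genes may be present under another name. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry.

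Genes named below are the 25 coding sequences with the highest mean TPM in intact plate spores, the up to 10 largest changes per direction and contrast among genes past the threshold with a mean of at least 50 counts and no overlap between groups (where fewer than 3 pass, the 3 smallest p, said not to pass), a fixed set of marker genes, and list members with the smallest p. Members of the 52 genes outside this rule, and other genes outside it, were named after their values were seen. The alternatives were DESeq2 1.42.0 size factors and test, library size alone, no filter, at least 50 counts, limma on RPKM with pseudocounts of 0.1, 1 and 10, an additive design, all features, library sizes without the 20 most abundant genes, a replicate block, pooled contrasts, and leaving out each replicate. Chosen after seeing the data were the 52-gene fits, a fit of the genes left by background removal with their counts as deposited, and the removal of an even background, taken as the median reads per base of genes under 300 reads in every library. Figures were drawn with matplotlib 3.10.9. Splice forms, transcript ends and reads outside features were not analysed here.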

Results

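Messenger RNA was counted in 9 libraries of dormant Bacillus subtilis PS533 spores to learn which transcripts spores hold and whether these differ with the sporulation medium, the spore coat and the purification. Coding reads numbered 635129, 965969 and 1659560 in the 3 libraries of intact plate spores, 7355997 and 6236006 in the 2 of less well purified liquid spores, and 5449198 in intact highly purified liquid spores. The decoated libraries held 2925681 (1-day plate spores), 2055103 (7-day plate spores) and 1683660 (7-day liquid spores). Ribosomal RNA took 80.9%, 66.0% and 8.49% of gene reads in plate replicates 1, 2 and 3, and 2.28% to 12.4% in the other 6 libraries. Library titles carry 1 date for the intact plate spores and another for the intact liquid spores, and none for the decoated spores. The title date therefore cannot be separated from the medium in intact spores. Only purity in liquid is compared within 1 date, and whether the decoated libraries share a set with each other or with the rest is not given.

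A few short transcripts made up nearly all coding reads of intact spores. The most abundant by TPM in plate spores were ypzF and ypzG, then sspE, which encodes the gamma-type small acid-soluble spore protein (SASP), ykzP and ykzE. In plate spores sspE took 14.7% ± 1.13 of coding reads, ypzF 12.2% ± 0.319, ypzG 9.98% ± 0.711, ykzP 7.50% ± 0.100 and ykzE 4.81% ± 0.150 (SD, n = 3). The other 20 of the top 25 were, in order, ytzC, sspT, sspN, yfhD, yhcV, ytzL, sspJ, sspF, sspO, sspP, ymfJ, yhdB, yrzQ, yizC, yqfX, sspM, sspK, sgpA, yrzR and BSU_18596. These 25 genes held 93.1%, 96.2% and 95.8% of coding reads in the 3 plate libraries. They were also the 25 most abundant in each decoated library and shared 22 genes with the top 25 of each intact liquid library. On the ASM904v1 chromosome sspE (BSU_08660) lies at 937900 to 938154, ypzF at 2311986 to 2312132, ypzG at 2329870 to 2330022, and the neighbours ykzP and ykzE at 1417561 to 1417716 and 1417719 to 1417895.

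Grouped by the fixed lists, the 16 matched SASP genes held 25.8% ± 1.10 of coding reads in plate spores, leaving out sspT (5.10% ± 0.235), which was not matched to the list and is in no SASP count here, and the 32 other sigma G genes of the forespore 9.84% ± 0.533 (SD, n = 3). Lists of growing and mother cell functions held small shares in intact plate spores. The largest was that of glycolysis genes, 0.141% ± 0.0068 (SD, n = 3), similar in the 3 replicates, against 0.0166% ± 0.0018 in less well purified liquid spores (SD, n = 2). Few genes carry it in plate spores, pdhA (share given below) among them. The median glycolysis gene had 6.22, 2.79 and 7.80 reads per kilobase in the 3 replicates, against 47.7, 66.0 and 120 over the list as a whole. The share therefore does not describe glycolysis genes as a class. Ribosomal protein genes together took 0.0125% ± 0.0056, genes of the late mother cell and coat under sigma K 0.0415% ± 0.016, and germination genes 0.0109% ± 0.0091 (SD, n = 3). The means of the ribosomal protein, sigma K and germination lists rest partly on plate replicate 1. There germination genes took 0.0214%, against 0.0064% and 0.0050% in replicates 2 and 3. Ribosomal protein genes took 0.0187% against 0.0079% and 0.0108%, and sigma K genes 0.0600% against 0.0322% and 0.0324%. Single markers had few reads in the 3 plate libraries: hag (flagellin) 2, 0 and 2, rpsL (a ribosomal protein) 0, 1 and 1, gapA (glycolysis) 1, 0 and 10, and gsiB (general stress) 1, 0 and 0. The germination genes gerAA, spoVAC and gerD had 3, 0 and 0, then 6, 4 and 4, then 4, 2 and 4 reads. The coat genes cotG, cotX and cotZ had 41, 30 and 59, then 19, 13 and 37, then 2, 0 and 2 reads. A count of 0 allows up to 4.72, 3.11 and 1.81 CPM in these libraries, so low levels of such mRNAs were not detectable at this depth. Reads were found for all but 856, 3325 and 3187 coding sequences in plate replicates 1, 2 and 3.

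**Figure D1:**
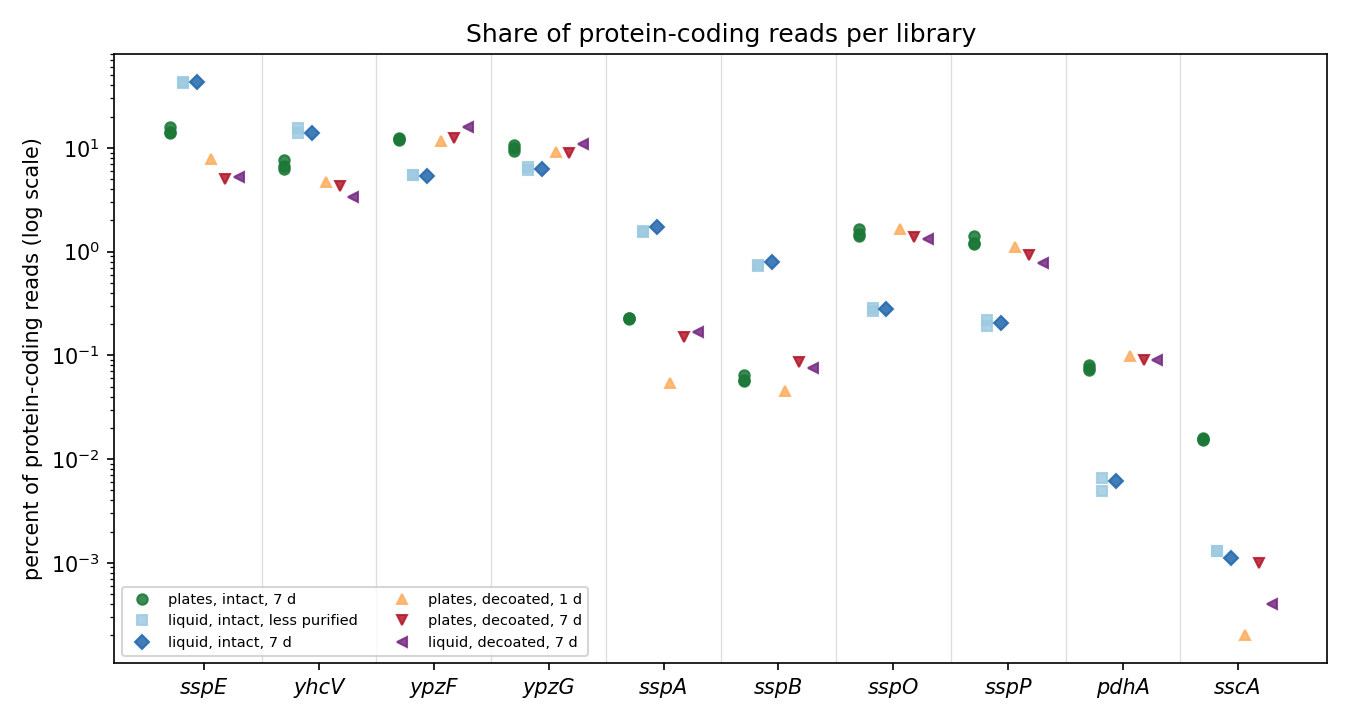
Percent of coding reads held by 10 transcripts in each of the 9 libraries, on a log axis, with 1 point per library coloured by group. sspE lies near 14.7% in intact plate spores and near 42.9% in intact liquid spores, and the 3 decoated libraries lie between 4.99% and 7.85%.

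Spores made on plates and in liquid held different proportions of the abundant mRNAs when left intact and highly purified. The alpha/beta-type SASP genes sspA and sspB, whose proteins coat spore DNA, stood out: sspA took 0.228% ± 0.0038 of coding reads in plate spores (SD, n = 3) and 1.73% (95% Wilson interval 1.72 to 1.74) in liquid spores. The share of sspB was 0.0596% ± 0.0040 (SD, n = 3) against 0.784% (0.777 to 0.792), and sspE, at 14.7% in plate spores, took 42.8% (42.80 to 42.88) in liquid spores. In the other direction pdhA, a subunit gene of pyruvate dehydrogenase, took 0.0762% ± 0.0039 in plate spores (SD, n = 3) and 0.0061% in liquid spores, and sspO and sspP, minor SASP genes, took 1.51% ± 0.112 and 1.27% ± 0.111 against 0.281% and 0.203%.

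In the 52-gene edgeR fit of this comparison 34 genes changed, 15 higher and 19 lower in plate spores; with library size alone 34 were higher and 8 lower, and scaled to rnpB 6 and 33. Relative to the median of the 52 genes, sspB was lower by a log2 change of −4.52 ± 0.107 (SE; adjusted p = 2.06e-07), sspA by −3.73 ± 0.067 (adjusted p = 7.16e-08), sspE by −2.34 ± 0.132 (adjusted p = 1.04e-05) and yhcV, a gene with CBS domains, by −1.81 ± 0.147 (adjusted p = 5.79e-05). Higher in plate spores were sscA, a small spore coat protein gene, by 3.01 ± 0.147 (adjusted p = 1.04e-05), BSU_18596 by 2.85 ± 0.805 (adjusted p = 0.0253), pdhA by 2.84 ± 0.252 (adjusted p = 1.68e-04), sspP by 1.84 ± 0.129 (adjusted p = 7.43e-05) and sspO by 1.62 ± 0.105 (adjusted p = 5.79e-05). Each of these moved the same way in 3 of 3 plate libraries against the liquid library. Of the 13 SASP genes among the 52, 4 were higher, 5 lower and 4 not called. The 7 other sigma G genes split into 3 higher, 3 lower and 1 not called. Directions for 14 of the 34 genes also passed the test with library size alone and with scaling to rnpB: BSU_18596, pdhA, sscA, sspO, sspP and yraG higher, and bsrH, sgpA, sspA, sspB, sspE, yhcV, yqfX and yrrD lower. The other 20 depend on the scaling. Without plate replicate 1, BSU_18596 no longer passed, at 2.79.

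Over all genes tested, 0 were called higher and 27 lower in plate spores (edgeR), with 122 at an unadjusted p under 0.05; DESeq2 called 23 higher and 13 lower. Among the lower genes were ylxP and its neighbours infB and rbfA, which encode a small protein of an RNA-binding family, translation initiation factor IF-2 and a ribosome-binding factor and lie side by side from 1734009 to 1736804. ylxP had 4, 8 and 14 reads in plate spores and 635 in liquid spores (log2 −5.58 ± 0.791, adjusted p = 5.03e-09), and infB 23, 11 and 23 against 803 (−4.87 ± 0.742, adjusted p = 5.36e-08). For rbfA the change was −3.74 ± 0.685 (adjusted p = 3.32e-05). The germinant receptor gene gerBC had 6, 6 and 4 reads against 203 (−4.66 ± 0.955, adjusted p = 3.44e-04). sspB, sspA, maeC (−4.28), yitF (−4.10), ywbA (−3.98) and secY (−3.74) complete the 10 largest. These changes stand beside a median of −0.49 over all genes tested. None passed in the other direction: the smallest p belonged to gerE, the late mother cell regulator (5.07 ± 1.60, adjusted p = 0.125), yrpDX (5.48, adjusted p = 0.175) and cotV (3.81, adjusted p = 0.324). The number of calls fell to 2 without plate replicate 2, to 3 without either less well purified liquid library and to 9 without plate replicate 3, and rose to 49 without plate replicate 1. ylxP and infB passed without each of these 5 libraries, and sspB was lost without plate replicate 2 (−5.06). rbfA, maeC and yitF were lost without plate replicate 2 (−3.28, −3.83 and −3.56) or either less well purified library, and sspA, gerBC, secY and ywbA in those 3 cases and without plate replicate 3 (−4.54, −4.07, −3.95 and −3.69). With library size alone 28 genes were called higher and 6 lower, sspB (−3.72) and sspA (−2.92) among them, while ylxP (−3.91), infB (−2.85), rbfA (−2.13) and gerBC (−2.64) did not pass. limma on RPKM called 31 higher and 17 lower.

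Against less well purified liquid spores, the only comparison with replicates on both sides, sspA, sspB and sspE were also far below the liquid level in plate spores. The plate libraries are the same as in the comparison above, so the 2 are not independent. Medium, purity and title date differ together here. The share of sspA was 0.228% ± 0.0038 (SD, n = 3) against 1.56% ± 0.0083 (SD, n = 2), that of sspB 0.0596% ± 0.0040 (SD, n = 3) against 0.733% ± 0.0038 (SD, n = 2), and that of sspE 14.7% ± 1.13 (SD, n = 3) against 42.9% ± 0.744 (SD, n = 2). In the 52-gene fit 16 genes were higher and 22 lower in plate spores (edgeR), against 34 and 8 with library size alone and 9 and 32 scaled to rnpB. Relative to their median, sspB was lower by −4.43 ± 0.098 (adjusted p = 1.39e-07), sspA by −3.59 ± 0.060 (adjusted p = 4.77e-08) and sspE by −2.35, while pdhA was higher by 2.92 ± 0.188 (adjusted p = 2.98e-05) and sscA by 2.77. Of 13 SASP genes 5 were higher, 6 lower and 2 not called. Under all 3 scalings 17 genes kept their call: BSU_18596, pdhA, sscA, sspO, sspP, yozQ, yraD, yraE and yraG higher, and bsrH, sgpA, sspA, sspB, sspE, yhcV, yqfX and yrrD lower. Over all genes tested 2 were higher and 35 lower (edgeR), around a median of −0.20. The largest were yhcT (−5.47 ± 1.13, adjusted p = 3.01e-04), sspB (−5.13), ylxP (−5.00 ± 0.725, adjusted p = 1.27e-08), cggR, the repressor of the gapA operon (−4.63), infB (−4.35), sspA (−4.32), lutC (−4.27), gerBC (−4.16), maeC (−4.08) and yitF (−3.61) among the lower. Among the higher, BSU_18596 met the naming rule (2.19 ± 0.644, adjusted p = 0.0495), yrpDX was called (5.81 ± 1.33, adjusted p = 0.00201) but had too few reads for it, and pdhA missed the threshold (2.14, adjusted p = 0.0584). The count fell to 1 without less well purified replicate 2, to 3 without replicate 1, to 2 without plate replicate 2 and to 14 without plate replicate 3, and it rose to 71 without plate replicate 1. ylxP passed without each of them. infB was lost without less well purified replicate 2 (−3.72), and sspB without it (−4.60) or plate replicate 2 (−4.90). yhcT, cggR, lutC, maeC and yitF were lost without plate replicate 2 (−5.85, −3.91, −3.55, −3.76 and −3.19) or either less well purified library, and sspA and gerBC in those 3 cases and without plate replicate 3 (−4.34 and −3.69). BSU_18596 passed only with every library or without plate replicate 1, ranging from 1.75 without less well purified replicate 1 to 4.24 without replicate 2. With library size alone 39 genes were higher and 6 lower; sspA (−2.77), sspB (−3.62) and BSU_18596 (3.87) passed, and ylxP (−3.51), yhcT (−4.04) and infB (−2.50) did not. DESeq2 called 28 higher and 17 lower, and limma on RPKM 43 and 10.

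In decoated spores of the same age the medium made little measurable difference. sspE took 4.99% (95% Wilson interval 4.96 to 5.02) of coding reads in plate spores and 5.28% (5.25 to 5.31) in liquid spores, sspA 0.149% against 0.167%, and sspB 0.0869% against 0.0756%. Of the 52 genes, 2 changed, both higher in plate spores: sspF, a minor SASP gene, by 1.08 ± 0.099 relative to the median (edgeR adjusted p = 0.00136) and yqfX by 0.67 ± 0.087 (adjusted p = 0.00427). Library size alone gave 2 higher and 2 lower; with scaling to rnpB edgeR called 0, and both calls rest on 1 library per side. Over all genes tested edgeR called 0 genes, with 0 at an unadjusted p under 0.05, and DESeq2 called 0. The smallest p belonged to cgeA (1.52), lytH (0.82) and yczN (1.31) in one direction and yuzM (−1.23), sspH (−1.09) and yoyE (−1.04) in the other, each at an adjusted p of 1. On simulated data of this design that fit recovered 0% of 64-fold changes.

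The medium difference itself depended on decoating for 24 of the 52 genes (edgeR interaction, 16 positive and 8 negative). Scaled by library size alone, 8 were positive and 30 negative, and scaled to rnpB 16 and 2. The interaction, which is positive where the plates-to-liquid difference was raised by decoating, was 4.89 ± 0.190 (log2 relative to the median, SE) for sspB (adjusted p = 4.42e-06), 3.73 ± 0.117 for sspA (adjusted p = 2.32e-06) and 2.42 ± 0.229 for sspE (adjusted p = 2.87e-04), and −2.67 ± 0.348 for pdhA (adjusted p = 0.00177). Of 13 SASP genes 4 were positive, 3 negative and 6 not called. Calls for bsrH, sgpA, sspA, sspB, sspE, yhcV, yqfX and yrrD (positive) and pdhA and yraG (negative) held under all 3 scalings. Across the 52 genes, which are not independent replicates, the medium difference in intact spores correlated with that in decoated spores at r = 0.071 (Spearman rho 0.010). Over all genes edgeR called 0 interactions, with 38 at an unadjusted p under 0.05, and DESeq2 called 0. The smallest p were those of sspB (4.96, adjusted p = 0.685), infB and ylxP (4.65), then yrpDX (−6.55), gerE (−4.76) and pdhA (−2.56). Without plate replicate 1 that count was 13. The decoated libraries also lack the title dates that the intact ones carry.

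**Figure D2:**
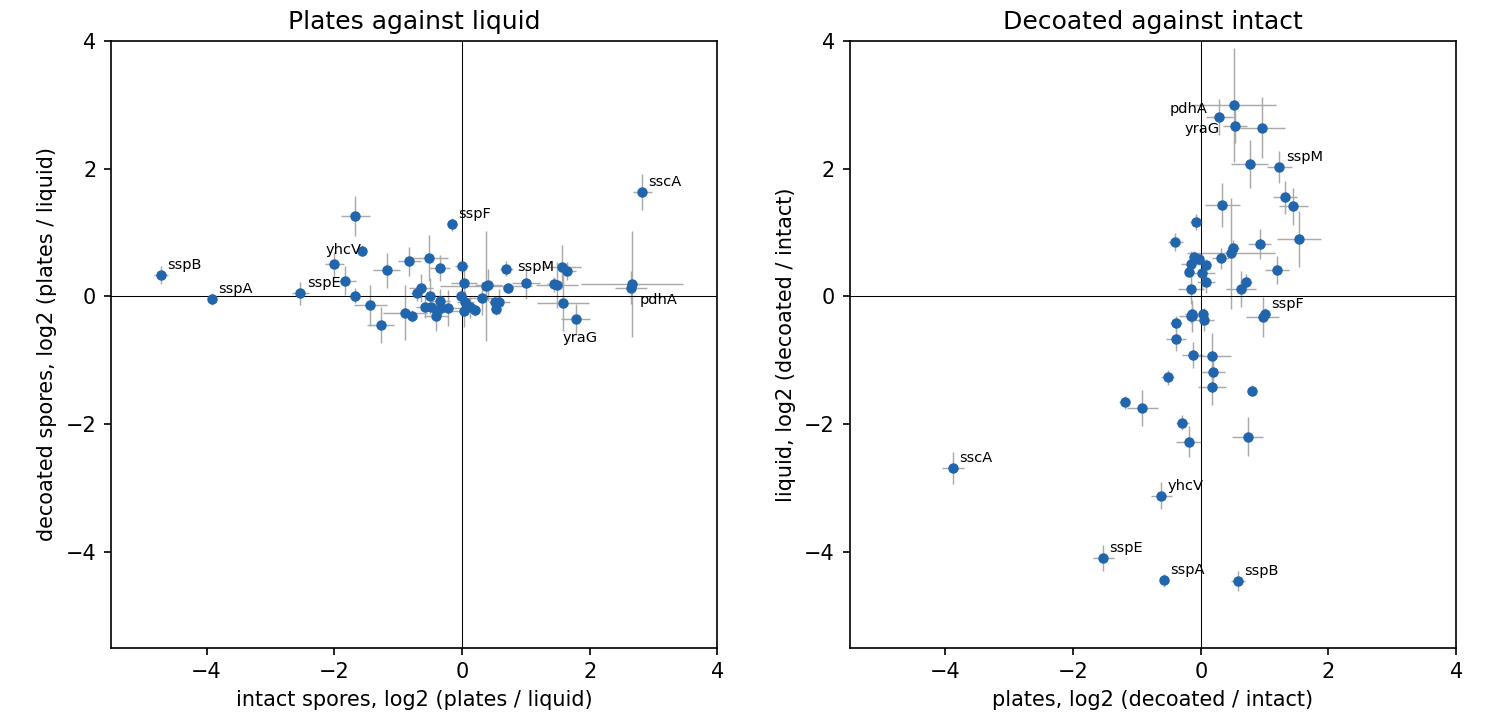
Fitted log2 differences of the 52 abundant genes, before the median is subtracted, with their standard errors; the left panel sets plates over liquid in intact spores (x axis) against decoated spores (y axis), and the right panel decoated over intact in plate spores (x axis) against liquid spores (y axis). sspA, sspB and sspE lie far left and near 0 in height in the left panel, where r is 0.071 across genes.

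Less well and highly purified liquid spores held nearly the same abundant mRNAs. sspE took 42.9% ± 0.744 (SD, n = 2) of coding reads in the former and 42.8% in the latter, ypzF 5.43% ± 0.0128 (SD, n = 2) against 5.30%, and yhcV 14.7% ± 1.09 (SD, n = 2) against 13.8%. None of the 13 SASP genes and none of the 7 other sigma G genes among the 52 was called. In the 52-gene edgeR fit 0 genes changed, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.957, and the largest fitted difference was 1.5-fold (yraE). On simulated data with 1 shared composition this fit recovered 100% of 2-fold changes for this comparison (7 of 7 genes). Over all genes edgeR called 0, with 10 at an unadjusted p under 0.05, and DESeq2 called 0, with 16. Those with the smallest p did not pass: cotG, a coat protein gene, had 206 and 601 reads in the less well purified libraries and 38 in the other (3.08 ± 1.04, adjusted p = 1), and the overlapping BSU_36079 shares its reads. cgeA (4.53), gerT (−3.34), htpG (−8.39) and ytdA (−7.17) follow. Without plate replicate 1 the edgeR count was 2.

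Decoating of plate spores went with a lower share of sspE and sscA and a higher share of several minor SASP genes. The decoated side is 1 library without the title date of the intact ones, so decoating cannot be separated from a difference in library set. sspE fell from 14.7% ± 1.13 (SD, n = 3) of coding reads to 4.99% (95% Wilson interval 4.96 to 5.02), and sscA from 0.0155% ± 0.0004 (SD, n = 3) to 0.0010%, or 21 reads. sspF rose from 2.44% ± 0.130 (SD, n = 3) to 4.77%, sspM from 0.269% ± 0.024 to 0.614%, and sspI from 0.0194% ± 0.0024 to 0.0472%. The 52-gene edgeR fit called 12 genes higher and 9 lower, against 12 and 11 with library size alone and 3 and 8 scaled to rnpB. Relative to the median, sscA changed by −3.96 ± 0.169 (adjusted p = 2.1e-05), sspE by −1.60 ± 0.160 (adjusted p = 7.49e-04), and yizC by −1.27, against yoyE at 1.46, sspI at 1.24 ± 0.193 (adjusted p = 0.00304), sspM at 1.15 and sspF at 0.93 ± 0.076 (adjusted p = 1.83e-04). Of 13 SASP genes 6 were higher, 4 lower and 3 not called. Under all 3 scalings the call held for 11 genes: sspI, ykzD and yoyE higher, and sscA, sspA, sspE, sspJ, yhcQ, yhcV, yizC and ytzC lower. So the direction of sspF and sspM passed the test under TMM but not under every scaling.

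Over all genes tested, sscA alone was called (−7.08 ± 1.34, edgeR adjusted p = 3.76e-04; 101 genes at an unadjusted p under 0.05), against 67 lower and 0 higher by DESeq2. The median over all genes was 1.24 here, and 0.75 for liquid spores. For plate spores the median of the 52 genes was −3.14 in this fit but 0.082 with library size alone, so the size of these changes depends on the scaling. The decoated 7-day plate library had reads on all but 1 coding sequence, and its 4140 low genes (under 300 reads in every library) carried 82.8 reads per kilobase against 1.08 to 5.47 in intact plate spores. Not passing were yuzM (−3.87, adjusted p = 0.147), yrpDX (−6.91), yeaA (7.10, adjusted p = 0.23), cotA (2.71) and ldeI (3.68). Without plate replicate 1 the count was 118. sscA passed without each replicate, but with library size alone, where 19 genes were higher and 7 lower, it changed by −3.88 and did not pass. limma on RPKM called 387 genes higher and 7 lower.

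In liquid spores sspE, sspA and sspB took a far smaller share in the decoated than in the intact library, while other SASP genes of similar abundance did not move together. Each side of this comparison is 1 library, and only the intact one carries a title date. Decoating therefore cannot be separated from a difference in library set. Odd counts made up 27.5% of nonzero counts under 1000 in the intact and 49.7% in the decoated library, so the counts may not be on 1 scale. sspA fell from 1.73% (95% Wilson interval 1.72 to 1.74) of coding reads in the intact highly purified library to 0.167%, sspB from 0.784% (0.777 to 0.792) to 0.0756%, sspE from 42.8% (42.80 to 42.88) to 5.28% (5.25 to 5.31), and yhcV from 13.8% to 3.35%. The share of sspJ went from 2.29% to 1.44%, that of sspF from 1.37% to 2.39% and that of sspN from 1.03% to 3.35%. The share of pdhA rose from 0.0061% to 0.0902%. In the 52-gene edgeR fit 18 genes were higher and 20 lower, against 33 and 10 with library size alone and 6 and 25 scaled to rnpB. Relative to the median sspB changed by −4.58 ± 0.163 (adjusted p = 3.64e-06), sspA by −4.57 ± 0.103 (adjusted p = 4.64e-07), sspE by −4.22 ± 0.202 (adjusted p = 1.44e-05), yhcV by −3.24 and sspJ by −1.87 ± 0.288 (adjusted p = 0.00229). sspN changed by 0.50 ± 0.087 (adjusted p = 0.00113) and sspF by −0.40 ± 0.098 (−0.28 before the median is subtracted, to which the adjusted p of 0.0423 belongs), opposite in sign to its share of reads, so its direction depends on the scaling, while pdhA changed by 2.69 ± 0.278 (adjusted p = 2.43e-04) and yraG by 2.54. Of 13 SASP genes 7 were higher, 5 lower and 1 not called, and of 7 other sigma G genes 3 were higher, 3 lower and 1 not called. Calls held under all 3 scalings for 16 genes: BSU_18596, pdhA, sspM, yraD, yraE and yraG higher, and bsrH, sgpA, sscA, sspA, sspB, sspE, yhcV, yizC, yqfX and yrrD lower. Across the 52 genes, which are not independent replicates, the change on decoating correlated between the media at r = 0.520 (rho 0.549).

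Over all genes 40 were lower and 0 higher in decoated liquid spores (edgeR, 126 at an unadjusted p under 0.05), and DESeq2 called 1 higher and 28 lower. The 10 largest were sspB (−7.61 ± 1.42, adjusted p = 1.1e-04), sspA (−7.61), ylxP (−7.38 ± 1.32, adjusted p = 6.76e-05), rbfA (−5.84), sigW, an extracytoplasmic sigma factor gene (−5.66), infB (−5.65), yuzM (−5.55), ykuS (−5.52), yrrD (−5.43) and metK, which encodes S-adenosylmethionine synthetase (−5.42). ylxP had 635 reads in the intact and 22 in the decoated library. The size of these changes depends on the scaling. The TMM factor was 0.249 in the intact and 4.803 in the decoated library. The median of the 52 genes was −3.04 in this fit but 1.23 with library size alone. With library size alone metK changed by −1.15, sigW by −1.41, yuzM by −1.29 and ykuS by −1.255. The higher genes with the smallest p, yfkN (9.40, adjusted p = 0.515), yodN (8.41) and pksM (3.32), did not pass. The count was 103 without plate replicate 1, 17 without plate replicate 3, 1 (ylxP) without plate replicate 2 or less well purified replicate 1, and 0 without less well purified replicate 2, when ylxP (−7.24) no longer passed. So sspB (−7.47) and the other 8 were lost in 3 of these 5 cases, and sspA (−7.46) and sigW (−5.52) also without plate replicate 3; none of the libraries left out is in the contrast itself, and the genes tested stayed the same. With library size alone 40 genes were higher and 8 lower; sspA (−3.34), sspB (−3.35) and yrrD (−1.16) passed, and ylxP (−3.12), rbfA (−1.57) and infB (−1.39) did not. limma on RPKM called 228 higher and 10 lower, mostly the opposite direction.

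**Figure D3:**
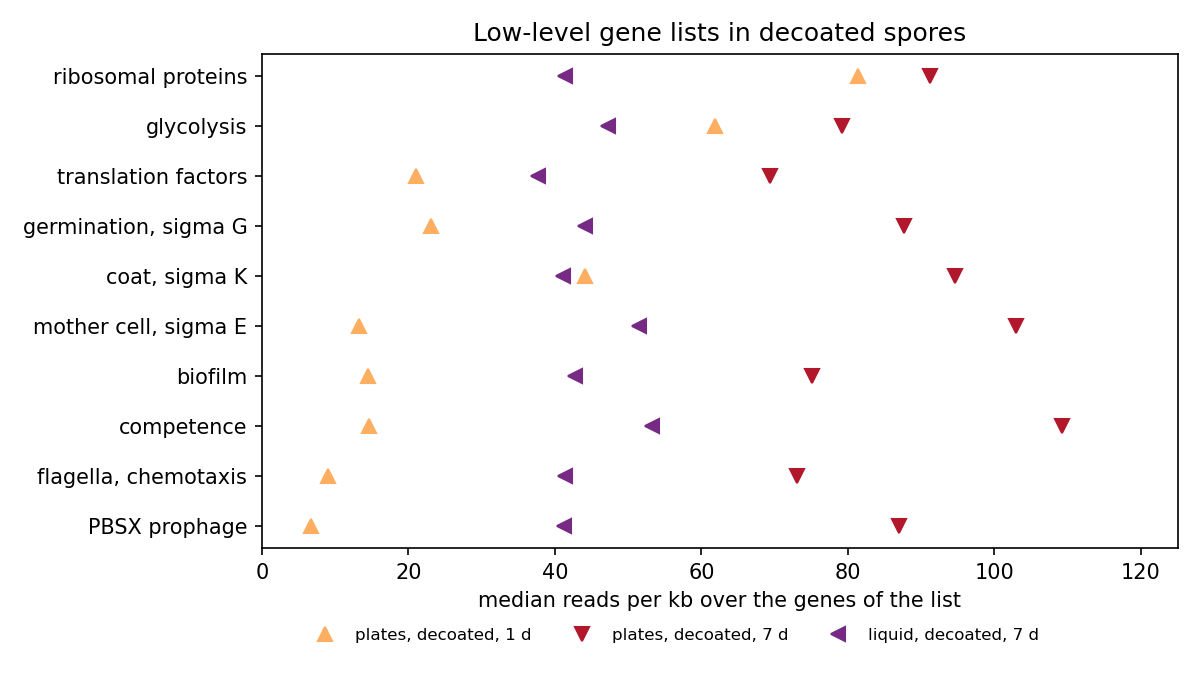
Median reads per kilobase of 10 gene lists in the 3 decoated libraries. In the 7-day plate library PBSX prophage genes lie at 86.95 and ribosomal protein genes at 91.28, and in the 1-day library at 6.73 and 81.35.

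The library of plate spores decoated after 1 day of purification had a higher share of cotG reads than that of spores purified for 7 days, and a lower share of the SASP gene sspA. Each side is 1 library. The 7-day spores are also labelled highly purified and the 1-day spores are not, so days and degree of purification cannot be separated. cotG had 1822 reads after 1 day and 80 after 7 days (623 and 38.9 CPM). The CPM ratio was 7.97 for cotA (outer coat laccase), 14.8 for gerT, 8.43 for cotM, 11.5 for cotZ, 5.58 for tufA, which encodes elongation factor Tu, and 8.81 for sigA, the gene of the main vegetative sigma factor. The late mother cell regulator gerE went the other way, at 1.71 CPM after 1 day and 39.4 after 7 days. Of the fixed markers, cotX had 88 reads after 1 day and 51 after 7 days, and spoVFA 56 and 65. Coding reads of these libraries numbered 2925681 and 2055103. An even background was estimated from low genes at 16.1 reads per kilobase in the 1-day and 81.6 in the 7-day library. It would bring 126 of the 138 cotA reads after 7 days but 18.4 of the 81 gerE reads. For cotZ (36.5 against 21 reads) and tufA (97.2 against 81) it exceeds the 7-day count, so their ratios have no measured denominator. Of these genes only cotG and sigA passed the test over all genes. Among the abundant mRNAs, sspA took 0.0537% of coding reads after 1 day and 0.149% after 7 days, sspF 2.62% and 4.77%, and yhcQ 1.37% and 0.601%. Over all genes tested edgeR called 3 higher after 1 day and 0 lower, with 107 at an unadjusted p under 0.05: cotG (6.05 ± 1.25, adjusted p = 0.00204), the overlapping BSU_36079 (6.08) and sigA (5.19 ± 1.28, adjusted p = 0.0466). DESeq2 called 29 higher and 1 lower. With library size alone 9 genes were higher and 6 lower, and cotG (3.96) and sigA (3.10) did not pass. srfAD (−4.25, adjusted p = 0.967), pksJ (−2.89) and srfAA (−2.18) had the smallest p in the other direction. The count was 105 without plate replicate 1, 2 without plate replicate 3, and 0 without plate replicate 2 or either less well purified library, when cotG stayed at 6.03 and sigA at 5.17 but neither passed; sigA was also lost without plate replicate 3. limma on RPKM called 9 higher and 58 lower.

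The 52-gene edgeR fit called 8 genes higher and 12 lower after 1 day, a balance that turns to 20 and 5 with library size alone and 23 and 2 scaled to rnpB. Relative to the median sscA changed by −2.64 ± 0.271 (adjusted p = 8.29e-04), sspA by −1.84 ± 0.093 (adjusted p = 3.81e-05), sspB by −1.32 ± 0.145 and sspF by −1.23 ± 0.100 (adjusted p = 2.74e-04), against yjzC at 1.40, yrzB at 1.31, yraG at 1.23 ± 0.229 (adjusted p = 0.0096) and yhcQ at 0.82 ± 0.123 (adjusted p = 0.0073). Of 13 SASP genes 0 were higher and 4 lower, with 9 not called, and of 7 other sigma G genes 2 were higher. Under all 3 scalings 10 calls held: yhcM, yhcQ, yizC, yjzC, ymfJ, ypzI, yraG and yrzB higher, and sscA and sspA lower. For sspB and sspF the call depends on the scaling.

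Of 160 tests of the 20 lists over 8 contrasts, camera called 29 at its preset correlation, 8 up and 21 down. None was called with an estimated correlation, where the smallest adjusted p was 0.293, and none by fry, where it was 0.209. In intact plate spores against highly purified liquid spores, sigma K genes were up (adjusted p = 4.14e-05; adjusted p = 0.798 with an estimated correlation; gerE and cotV had the smallest p). Down were RNA decay genes (adjusted p = 0.0429), sigma F genes (0.0429) and germination genes (0.0442), with adjusted p of 0.798, 0.798 and 0.961 with an estimated correlation. Of the germination genes 1, gerBC, was called over all genes and 1 adjusted over the list alone; sigma F genes had 0 and 4, RNA decay genes 0 and 2. SASP genes were not called there as a list, with 3 lower over all genes and 3 adjusted over the list alone. Against less well purified spores, SASP genes were down (adjusted p = 0.0107; adjusted p = 0.903 with an estimated correlation), 3 of them over all genes and 4 adjusted over the list alone. Sigma F genes (adjusted p = 0.00111) and germination genes (0.0344) were down too, at adjusted p of 0.707 and 0.903 with an estimated correlation. SASP genes were down in decoated plate against decoated liquid spores (adjusted p = 2.95e-05; adjusted p = 0.983 with an estimated correlation), although their 13 members among the 52 had a median of 0.083, with 1 higher and 0 lower. Sigma K genes were up in less well purified spores (adjusted p = 0.00759; adjusted p = 1 with an estimated correlation). The interaction was up for RNA decay genes (adjusted p = 0.0454) and down for sigma K genes (adjusted p = 0.00703), each at an adjusted p of 0.992 with an estimated correlation.

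The lists called for decoating were all down, measured against the other genes tested, whose reads rose on decoating. In plate spores SASP genes had an adjusted p of 7.93e-22 (median log2 −2.64; adjusted p = 0.293 with an estimated correlation), with 0 genes called over all genes and 13 lower adjusted over the list alone. Among the 52 genes, SASP members instead had a median of 0.23 relative to the 52, and of 0.48 in liquid spores. Other sigma G genes (adjusted p = 9.09e-12; 6 lower adjusted over the list alone), glycolysis genes (3.71e-05; 3 lower) and sigma F genes (0.00401) each had an adjusted p of 0.293 with an estimated correlation. For sigma K genes (adjusted p = 7.66e-04; adjusted p = 0.727 with an estimated correlation) the median, 0.90, and the mean, 0.086, have the opposite sign to the test. Ribosomal protein genes (adjusted p = 0.021; adjusted p = 0.727 with an estimated correlation) had a median of −0.10 and a mean of 0.28. In liquid spores SASP genes (adjusted p = 1.23e-12; 3 lower over all genes and 10 adjusted over the list alone), other sigma G genes (1.75e-07; 3 and 9), sigma F genes (7.34e-04; 2 and 2), germination genes (0.00531; 1 and 1) and glycolysis genes (0.0473; 0 and 0) had an adjusted p of 0.585 with an estimated correlation. Ribosomal protein genes (adjusted p = 0.0431) and translation factor genes (0.0431, with infB called) had 0.716 and 0.844 as adjusted p with an estimated correlation. After 1 day against 7 days the called lists were all up: SASP genes (adjusted p = 8.9e-08; 1 higher adjusted over the list alone, although 4 were lower among the 52 genes), other sigma G genes (2.15e-05; 8 higher adjusted over the list alone and 0 over all genes), ribosomal protein genes (0.00509; median 1.75), sigma K genes (0.0101; 1 over all genes and 4 adjusted over the list alone) and glycolysis genes (0.0149), each at an adjusted p of 0.638 with an estimated correlation. The remaining 11 lists were not called in any contrast. Their smallest adjusted p were 0.0507 for flagella and chemotaxis, 0.0694 for cold shock, 0.0929 for sigma E, 0.12 for the PBSX prophage, 0.125 for heat shock, 0.146 for sigma B, 0.389 for competence, 0.425 for biofilm and cannibalism, 0.475 for the TCA cycle, 0.585 for early sporulation and 0.708 for ATP synthesis and respiration.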

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

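Of the tests in this part, the one with libraries thinned to a common depth was written before its result was seen; the others were chosen after.

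The difference between plate and liquid spores differed between intact and decoated spores for 24 of the 52 abundant genes, by a test of the interaction itself (edgeR), which was 5.04 (log2) for sspB, 3.88 for sspA, 2.58 for sspE and −2.52 for pdhA before the median of 0.15 is subtracted. The medium differences of the 52 genes correlated at 0.071 between the coat states (bootstrap interval over genes −0.249 to 0.378). This value restates the interaction and cannot decide whether a medium effect is alike in intact and decoated spores. In intact spores the title date differs with the medium, and decoated spores have 1 library per medium. Unequal depth is argued against, since 23 genes had an interaction after every library was thinned to the smallest. The library set cannot be told apart from the medium: if the undated decoated libraries are taken as 1 set, pairs of 1 set and different medium, all decoated, correlated at 0.987 on average and pairs of 1 medium and different sets, all differing in decoating, at 0.923. That last mean hides a split. The decoated liquid library correlated at 0.948 to 0.959 with intact plate libraries, but at 0.864 to 0.886 with intact liquid libraries of its own medium. For the decoated 7-day plate library the values were 0.962 to 0.969 and 0.874 to 0.896. The intact liquid libraries, which share 1 title date, thus stood apart from both media. An effect of sporulation medium on intact spores that decoating removes, or RNA lost in decoating, may account for the interaction as well and was not tested.

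The contrast of plate and liquid spores among the 6 intact libraries, 3 against 3, called 86 genes over all genes and 40 of the 52. Of the 10 splits 1 gave as many in each set, the real one, and the highest other split gave 0 and 0; with 10 splits a share under 0.05 cannot be reached.

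The 7-day decoated libraries had reads on nearly all coding sequences, unlike intact spores. RNA of growing cells is argued against, because ribosomal protein genes, abundant in such cells, had 1.05 times the median reads per kilobase of PBSX prophage genes in plate spores and 1.003 times in liquid spores, with bootstrap intervals up to 1.263 and 1.377. The same ratio inverted, 0.953 and 0.997 and so no separate evidence, is near the equal level that an even background such as genomic DNA needs, which may be part of the source, but reads followed gene length less (Spearman 0.777 over 4140 low genes in plate spores) than a simulated even background (0.981). A broad low-level set of spore mRNAs stays open, since the deposited values hold neither strand nor reads between genes. Simulated gene-specific levels gave 0.308. The spread of reads per kilobase over low genes (coefficient of variation 0.568) was nearer the simulated even background (0.153) than the gene-specific levels (5.139). The spread of those levels was a chosen setting, and the even background held counting error alone, so neither simulation decides. Taking an even background off (16.1 reads per kilobase in the 1-day and 81.6 in the 7-day plate library) left 859 genes to test and moved their decoating calls from 1 to 27 in plates and 45 to 65 in liquid, while all 21 and 38 calls of the 52 genes kept their direction and passed, 1 was gained (sgpA), and the called genes shifted by at most 0.088 (log2) except sscA.

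In the 1-day decoated library, sigma K and ribosomal protein genes stood above other low genes, at a median of 44.1 and 81.4 reads per kilobase. The median was 16.1 over the 4140 low genes and 6.73 for the PBSX prophage, the lowest of the 20 lists there. Multiples of the PBSX level are therefore larger than multiples of the low-gene median would be. RNA of mother cells left around the spores meets the 1 value asked of it but is not singled out: the 48 sigma K genes, 1 of them in another list, were 6.55 times the PBSX level (bootstrap interval 2.915 to 12.082), with cotG at 1822 and cotA at 1565 reads, but sigma E genes of the same cell stood at 1.97 times (0.886 to 5.323). Sigma F genes of the forespore had a median of 48.1 reads per kilobase, so a level above PBSX does not mark the mother cell, whose remains the density gradient of the highly purified groups is meant to remove. Motile growing cells cannot be told apart, as flagella and chemotaxis genes stood at 1.337 times the PBSX level (0.633 to 2.066), with hag at 18 reads. A change of the spores' own mRNA with time of storage and washing stays open, untested, since the group has 1 library.

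Structural RNAs lie outside the comparisons of coding genes and were above the limit that a count of 0 allows in every library. The fewest reads in any library were 431436 for scr, 378239 for rnpB, 206000 for ssrA, 2119 for ssrSA, 4089 for ssrSB and 142 for csfG. No group holds 4 to 10 libraries, so no single library was tested as standing apart from its group.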

How the results depend on the processing

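The 52-gene fits, the removal of an even background and the fit of the genes left by it were chosen after the data were seen; the other alternatives were set before. Counts below are genes past an adjusted p of 0.05, beside 27 (intact medium, highly purified), 0 (decoated medium), 37 (intact medium, less well purified), 0 (purity), 1 (decoating, plates), 40 (decoating, liquid), 3 (purification time) and 0 (interaction) in the edgeR fit of all genes. The cause was not tested where none is named. For named genes, 35 results over all genes gave 496 values under alternatives that passed in the same direction, 230 that missed the threshold and 0 that reversed; 117 results relative to the 52-gene median gave 1435, 1547 and 6.

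DESeq2 size factors gave 10 (5 higher) for the intact medium and 5 for decoating in liquid. Without a filter the counts were 17 and, for less well purified spores, 23, and 14 for decoating in liquid. Requiring 50 counts in 3 libraries, which tests fewer genes (419), gave 78 and 79 for the intact medium, 41 and 71 for decoating in plates and liquid, 28 for purification time and 19 for the interaction. The DESeq2 test gave 67 for decoating in plates and 30 for purification time. limma on RPKM with a pseudocount of 1 gave 48 (intact medium), 16 (decoated medium), 9 (purity), 394 and 238 (decoating, plates and liquid), 67 (purification time) and 45 (interaction). It gave 53 against less well purified spores. Higher were 31 and 43 for the intact medium and 387 and 228 for decoating, and 58 were lower for purification time, mostly opposite to the calls of the fit of all genes. With a pseudocount of 0.1 these were 74, 14, 23, 183, 177, 49 and 54, and with 10 they were 40 for the decoated medium, 2318 and 1418 for decoating, 975 for purification time and 52 for the interaction. For the intact medium 41 of 74 and 43 of 54 were higher at 0.1, and 24 of 34 and 41 of 50 at 10. The opposite direction held for 178 and 168 of the decoating genes and 39 of the purification time genes at 0.1, and for 2303, 1407 and 867 at 10. Library size alone gave 34 (28 higher) and 45 (39 higher) for the intact medium, 5 (3 higher) for the decoated medium, 26 (19 higher) and 48 (40 higher) for decoating, 15 (9 higher) for purification time and 26 (21 negative) for the interaction. Leaving the 20 most abundant genes out of library sizes gave 14 and 19 for the intact medium and 13 for decoating in liquid. Testing all features gave 10 and 26 for decoating in plates and liquid.

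The additive design, which pools contrasts by construction, gave 5 for the intact medium, 5 for the decoated medium, 7 for less well purified spores, 53 for decoating in plates and 24 for purification time. Under it yqfX turned to −0.72 for the decoated medium and −0.12 for decoating in plates, and sspP to 0.025 for decoating in plates. The mean over intact and decoated spores gave 1 gene for the decoated medium, with yqfX at −0.41, and the mean over the 2 media 75 for decoating in plates, with yqfX at −0.49 and sspP at 0.086. Taking the 3 intact liquid libraries as 1 group gave 75 for the intact medium. The replicate block gave 27 genes for less well purified spores against 38 without it on the same 4 libraries; same-numbered libraries correlated at −0.145 over the 52 genes, and their numbers are only names.

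The 52-gene fit gave 2 for the decoated medium, 21 for decoating in plates, 20 for purification time and 24 for the interaction, with a smaller spread between replicates (common dispersion 0.025 against 1.184). With library size alone it gave 42 for the intact medium (34 higher, against 15 of 34), then 4, 23, 25 (20 higher, against 8 of 20) and 38 (30 negative, against 8 of 24). With an even background removed it gave 2, 22, 20 and 24, with counts halved 2, 21, 20 and 25, with libraries thinned to the smallest 5, 26, 20 and 23, and without plate replicate 1 it gave 3, 22, 18 and 22. Scaled to rnpB it gave 39 (6 higher) for the intact medium, 11 (3 higher) for decoating in plates, 25 (23 higher) for purification time and 18 (16 positive) for the interaction. Removing an even background from all genes, which leaves fewer to test (859), gave 74 (26 higher) and 83 (28 higher) for the intact medium, 27 (2 higher) and 65 (17 higher) for decoating in plates and liquid, 36 (27 higher) for purification time and 34 (22 positive) for the interaction. The same 859 genes with the background kept gave 34 (2 higher) and 51 (10 higher), then 1 and 45 (0 higher), 3 and 0.

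Leaving out each replicate in turn gave 2 to 49 (intact medium), 1 to 71 (less well purified), 0 to 2 (purity), 1 to 118 and 0 to 103 (decoating, plates and liquid), 0 to 105 (purification time) and 0 to 13 (interaction), and 0 each time for the decoated medium. The highest count came without plate replicate 1, the library with 80.9% ribosomal RNA. Leaving out plate replicate 2, with 66.0%, raised none of the counts. Replicate 1 also had low-level reads over most genes. It lacked reads for 856 coding sequences, against 3325 and 3187 in replicates 2 and 3. Its even background was 4.42 reads per kilobase against 0 and 0, and its TMM factor 1.739 against 0.756 and 0.568. Which of these matters was not tested. The 25 most abundant genes were the same without each replicate and by deposited RPKM, and 23 were shared by counts without length.

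Of the camera calls (4, 1, 3, 1, 6, 7, 5 and 2 lists in the contrasts in the order above), 0 were left in each contrast with an estimated correlation and 0 with fry. By share of summed TPM, SASP genes held 51.0% in intact highly purified liquid spores, 22.4% in 1-day, 20.6% in plate and 18.3% in liquid decoated spores. Other sigma G genes held 4.54% in plate, 9.96% in less well purified, 9.46% in highly purified liquid, 4.96% in 1-day, 4.18% in plate decoated and 3.01% in liquid decoated spores. TPM divides by length by construction, so short genes weigh more in it.

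Genes outside the 52 were measured less well. A level of 3 counts corresponds to 4.72 CPM in plate replicate 1, and in simulated data the all-gene fit recovered 0% to 53% of 64-fold changes depending on the contrast. How far depth, the common dispersion of 1.184 or groups of 1 library set this recovery was not tested.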

Other observations

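The comparisons with the PBSX prophage level in this part were chosen after the values were seen.

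Small stable RNAs were among the most abundant spore transcripts. scr, the RNA of the signal recognition particle, stood at 704 ± 39.4 reads per 1000 coding reads in intact plate spores (SD, n = 3), 287 ± 24.7 in less well purified liquid spores (SD, n = 2) and 266 in highly purified liquid spores, and at 493, 1376 and 574 in 1-day plate, 7-day plate and 7-day liquid decoated spores. rnpB stood at 674 ± 84.7 (SD, n = 3), 196 ± 18.5 (SD, n = 2) and 197 in the intact groups and at 628, 869 and 804 in the decoated ones. ssrA, the transfer-messenger RNA that rescues stalled ribosomes, stood at 340 ± 13.6 (SD, n = 3), 135 ± 9.20 (SD, n = 2) and 132, then 310, 538 and 336. The denominator itself moves between media with the share of sspE, so these ratios give no absolute level.

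The 6S RNA genes, whose products bind RNA polymerase, went different ways. ssrSA stood at 3.67 ± 0.378 reads per 1000 coding reads in intact plate spores (SD, n = 3) and 0.667 ± 0.067 in less well purified liquid spores (SD, n = 2), whereas ssrSB stood at 16.2 ± 3.37 (SD, n = 3) and 24.9 ± 0.895 (SD, n = 2). csfG, a small RNA gene of the forespore, stood at 0.194 ± 0.027 (SD, n = 3) and 0.763 ± 0.246 (SD, n = 2), with 142, 180 and 284 reads in plate and 6898 and 3674 in liquid libraries. In the fit of all features csfG was lower in plate than in less well purified liquid spores (log2 −3.34 ± 0.628, SE; edgeR adjusted p = 5.34e-05), while ssrSA (adjusted p = 0.924) and ssrSB (0.713) did not pass.

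In the 1-day decoated library other gene groups also stood above the PBSX prophage level: ribosomal protein genes at 12.1 times (bootstrap interval 6.04 to 20.2), glycolysis genes at 9.18 times (2.08 to 30.2) and germination genes at 3.43 times (1.56 to 5.47). Sigma E genes stood at 1.97 times (0.886 to 5.32), an interval that includes an equal level. The PBSX prophage had the lowest median of the 20 lists in this library, and the median over low genes was 16.1 reads per kilobase. Beside it, ribosomal protein genes had a median of 81.4, glycolysis genes 61.8, germination genes 23.1 and sigma E genes 13.3.

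Among nonzero counts, odd ones would be at least as frequent as even ones if each read were counted alone. Under 1000, odd counts made up 10.6% of nonzero counts in less well purified replicate 1. They made up 21.6% to 27.5% in the other intact libraries except plate replicate 1 (42.3%). In the 1-day plate, 7-day plate and 7-day liquid decoated libraries the share was 43.5%, 49.2% and 49.7%.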
